A study of Mus musculus with 3 samples.

How the data were processed

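RNA from follicle-associated epithelium of mouse small intestine was measured on 3 Affymetrix arrays, 1 from wild type and 2 from RBP-J depleted mice. Total RNA was extracted and turned into biotin-labelled cRNA, per the labels' protocols. The deposited values are linear intensities, 1 per probe set and array, made with MAS5, per the submitters' processing notes. Every array of the deposited table has a median of exactly 1 over its 45101 probe sets, so each intensity reads as a multiple of its array's median. Scanner files and detection calls were not used here. The 75th percentile was 4.19 in the wild type array, 4.05 in the first depleted array and 4.79 in the second, so scaling to the median left the upper part of the second depleted array brighter. No depth applies to arrays, and the number of arrays limits the precision.

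The labels give the genotype of each sample and number the 2 depleted samples. They do not say that these came from separate animals, so the spread between them may be technical. No p-value here can be taken to measure the spread between animals. Over the genes tested, Pearson's r of log2 intensities, across genes that are not independent replicates, was 0.951 between wild type and the first depleted array, 0.963 between wild type and the second, and 0.948 between the depleted arrays. No 2 arrays held the same values, and all 3 were used.

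Probe sets were named through the platform annotation paired with the table. Of 45037 probe sets that are not Affymetrix controls, 34945 had 1 gene symbol, 932 had several and 9160 were not listed and are unnamed here. Probe sets with several symbols or none stayed out of gene results. Of the probe sets with 1 symbol, 34741 matched a RefSeq gene of assembly GRCm38.p6 by Entrez number, which changed 0 symbols and gave the chromosome. Genes with several probe sets were represented by the probe set with the highest mean over the 3 arrays, which gave 18193 genes. The 11885 genes whose mean was at or above 0.598, the 40th percentile over all probe sets, were tested.

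Values were used as deposited, with no further scaling, as log2(value + 0.248). The pseudocount is the 25th percentile of all values, and folds of dim genes are understated on this scale. Depleted and wild type arrays were compared in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with an intensity trend. P-values were adjusted by Benjamini-Hochberg over the 11885 genes, and a gene was called at an adjusted p under 0.05. With 1 wild type array the spread comes from the 2 depleted arrays, with 1 residual degree of freedom per gene. To this eBayes added 600 prior degrees of freedom, so each gene's spread is mostly one pooled over genes along the intensity trend. The lone wild type array is assumed to vary like the depleted arrays. A count without a test took genes at least 2-fold from wild type in the same direction in both depleted arrays.

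The design, the tests, 32 gene lists and the rule for named genes were fixed before the data were examined. The lists were Notch target genes, Notch receptors, ligands and cofactors, secretory lineage transcription factors, goblet, Paneth, enteroendocrine, tuft, M cell, absorptive enterocyte and intestinal stem cell markers, epithelial chemokines, NF-kB signalling, antimicrobial and barrier defence, mucin glycosylation and membrane mucins, antigen presentation, interferon response, cell cycle, unfolded protein response, immediate early and heat shock genes, circadian clock genes, markers of B cells, plasma cells, T cells and intraepithelial lymphocytes, macrophages and dendritic cells, fibroblasts and lymphoid stroma, smooth muscle, endothelium, enteric neurons and glia, red blood cells and pancreatic acini, and, as checks, sex-linked and reference genes. The sex-linked and reference genes were not tested as sets. The 25 other lists with at least 5 tested members were tested with camera (limma) with a preset inter-gene correlation of 0.01. P-values were adjusted over the 25 lists, and the test was run again with an estimated correlation. With the preset correlation camera compares a list's genes with the other genes, so its p-values do not measure the spread between samples. As a description, each list's median log2 difference was placed as a percentile among the medians of 10000 random lists of the same size, matched on mean intensity in 20 bins. List members without a probe set of their own symbol were not analysed here.

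The named genes are Rbpj; the 12 genes with the largest rise and the 12 with the largest fall, ranked by the smaller of the 2 log2 differences from wild type, called genes first and then uncalled ones, leaving out immunoglobulin and predicted genes; up to 4 members of each list with the largest smaller difference in the same direction in both depleted arrays; any member of the Notch target, secretory transcription factor and epithelial chemokine lists; and the sex-linked and reference genes and Affymetrix controls. Other genes are named as chosen after their values were seen.

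Simulated arrays had the real genes' levels and 200 changed genes, over 20 runs on 11885 genes each. There limma called 21.8% of genes changed 2-fold and 95.5% of those changed 4-fold, and a mean of 6.05 unchanged genes per run. These rates hold for the simulated spread alone. Whether the real arrays, the lone wild type array among them, spread like the simulated ones was not tested. The mean of 6.05 came with 200 changed genes per run, so it gives no share of false calls among the 10 genes called in the real arrays. A raised list was called in 20 of 20 runs with the preset correlation and in 0 with an estimated correlation. With the preset correlation, 1 of 480 unchanged lists was called. An estimated correlation leaves the set test 1 residual degree of freedom and missed the raised list in every run, so its adjusted p-values decide nothing. Simulated genes were drawn independently, so 1 of 480 does not give the rate of false calls for lists whose genes move together.

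Alternatives fixed in advance were a pseudocount of 1 or at the median, quantile normalization, the same median or the same 75th percentile per array, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, no intensity filter or a filter at the 60th percentile, eBayes without trend or robust, the estimated correlation, and leaving out each depleted array. Alternatives added after the data were seen were a mean of at least 5, scaling to named genes with a mean of at least 5, leaving out X and Y linked genes, and a pseudocount of 5. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.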

Results

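Gene expression was measured in follicle-associated epithelium, the epithelial layer over the lymphoid follicles of Peyer's patches, which holds the antigen-sampling M cells. The tissue came from the small intestine of C57BL/6 mice. In the depleted mice, Rbpj had been removed by a Cre recombinase under the Villin promoter, which is active in intestinal epithelium. RBP-J is the DNA-binding protein through which Notch receptors act on transcription. The data are 1 array of wild type and 2 arrays of RBP-J depleted epithelium, all from untreated animals, and the question is which genes differ in this epithelium when RBP-J is depleted. Values are intensities in multiples of the array median, and differences are on the log2(value + pseudocount) scale, depleted minus wild type. The median log2 difference over all 11885 genes tested was -0.003 in the first depleted array and 0.22 in the second, and differences in the second are to be read against that shift.

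Rbpj itself was lower in the first depleted array than in wild type. In the second its probe sets gave log2 differences of -0.31, -0.12 and 0.14, all under that array's median of 0.22 over all genes. The brightest Rbpj probe set read 7.15 in wild type, 2.72 in the first depleted array and 5.74 in the second (log2 difference -0.81, SE 0.49, limma adjusted p = 0.9997), a difference that did not pass the test. Another Rbpj probe set read 5.37, 4.14 and 4.92 in the same order, and the remaining one 3.79, 2.30 and 4.21. Where these probe sets lie relative to the deleted part of the gene is not given in the sources used here, and a probe set outside that part does not check the deletion.

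The largest log2 differences were those of the sex-linked genes Xist, Eif2s3y and Kdm5d. That of Uty, also sex-linked, was -2.83, and -1.73 with a pseudocount of 1, where that of Mt1, at 2.57, was larger in size. Xist, the RNA that coats the inactive X chromosome in females, read 0.297 in wild type and 42.8 and 43.4 in the depleted arrays. Eif2s3y, Kdm5d and Uty, which lie on the Y chromosome, read 20.6, 8.03 and 3.02 in wild type. In the depleted arrays Eif2s3y read 0.122 and 0.056, Kdm5d 0.023 and 0.018, and Uty 0.219 and 0.206. All 4 genes were called by limma, with Uty at the highest adjusted p of 0.0157. Genotype and these sex-linked genes therefore split the 3 arrays the same way, and no array of either genotype breaks that split.

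Outside X and Y, 6 genes were called. Mt1, a metallothionein that binds zinc and copper, rose from 15.8 to 102 ± 39.8 (SD, n = 2), a log2 difference of 2.62 (SE 0.40, limma adjusted p = 3.05e-07). Pla2g4c, a cytosolic phospholipase A2, rose from 0.996 to 8.76 ± 4.66 (log2 difference 2.75, SE 0.50, limma adjusted p = 1.15e-04). Lce3f, a late cornified envelope gene, was called at 0.126 in wild type against 1.19 and 3.11 (limma adjusted p = 0.0273), and Vav3 at 0.067 against 1.26 and 2.02 (limma adjusted p = 0.0427). Both wild type values lie under the pseudocount, which sets the size of these differences: 2.55 for each gene on the log2 scale, and 1.41 for Lce3f and 1.29 for Vav3, uncalled, with a pseudocount of 1. Hspa1b and Hspa1a, near-identical genes for inducible Hsp70, fell by 2.62 (SE 0.48, limma adjusted p = 1.46e-04) and by 2.17 (SE 0.51, limma adjusted p = 0.0273) on the log2 scale.

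Other probe sets of the called genes did not all go the same way. A dimmer probe set of Mt1 and one of Pla2g4c were also higher in both depleted arrays, by 2.49 and 2.69 and by 2.03 and 1.55 on the log2 scale. For Vav3, the other probe sets gave 0.44 and 0.10, and -0.55 and -0.95. Hspa1a and Hspa1b transcripts are nearly the same, so it is uncertain which of the pair each probe set measured. Mt2, the neighbour and close relative of Mt1, chosen after its values were seen, read 13.4 in wild type and 5.39 and 13.3 in the depleted arrays, and was not called.

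In all, limma called 10 genes, 5 higher and 5 lower in the depleted arrays, and 270 genes had an unadjusted p under 0.05. The lone wild type array is assumed to vary like the depleted arrays. The count was 4 with quantile normalization and with the same 75th percentile per array, where Xist, Eif2s3y, Kdm5d and Mt1 remained, and 1, Xist, with no intensity filter. The lost calls kept differences of similar size. With quantile normalization the log2 difference was -2.74 (SE 0.52) for Hspa1b, -2.27 (SE 0.42) for Hspa1a and 2.74 (SE 0.55) for Pla2g4c, and with the same 75th percentile -2.69, -2.24 and 2.69. The prior degrees of freedom that limma gave its spread fell from 600 to 7.96 with quantile normalization, 15.2 with the same 75th percentile and 6.54 with no filter. By eBayes without trend they were 32.3, with 10 calls.

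**Figure D1:**
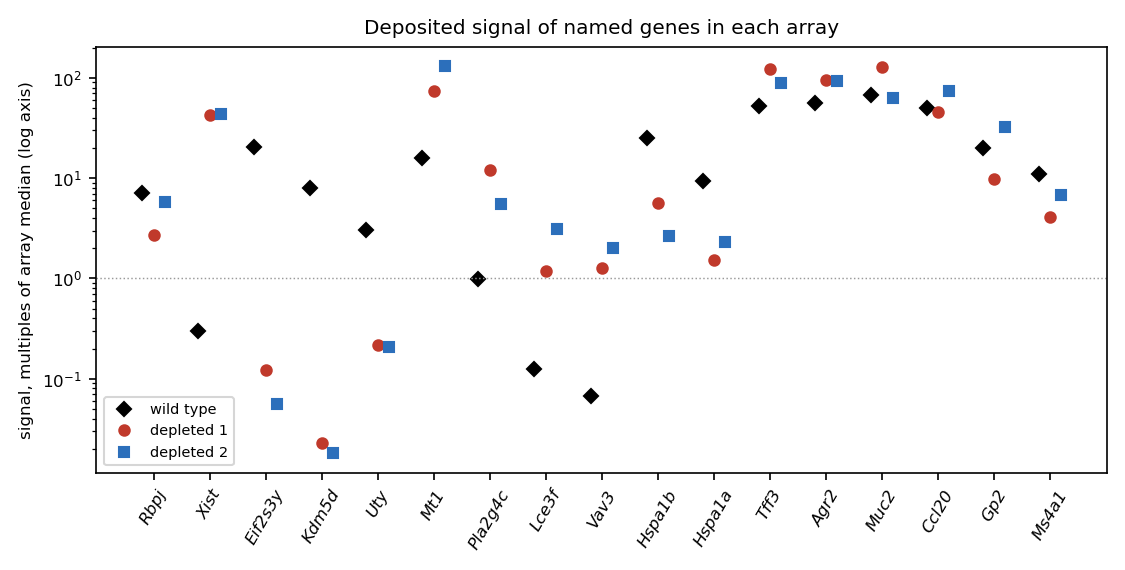
Deposited signal of 17 named genes in the wild type array (diamonds) and the first and second depleted arrays (circles and squares), in multiples of the array median on a log axis, with the array median as a dotted line. Xist lies at 42.8 and 43.4 in the depleted arrays against 0.297 in wild type, and Eif2s3y, Kdm5d and Uty lie above the array median in wild type alone.

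Fewer than 12 genes were called in either direction, so the next genes by rank are uncalled. The higher ones were Chac1, which degrades glutathione, the homeobox gene Hoxa3, the MAP kinase phosphatase Dusp4, Pym1, Dok7, the HLH inhibitor Id4 and Pced1a. The smaller of their 2 log2 differences lay between 1.53 for Pced1a and 2.08 for Chac1. Chac1, Hoxa3 and Dok7 read 0.249, 0.157 and 0.274 in wild type, close to the pseudocount or under it, so the size and rank of their differences depend on it. The other probe sets of Pced1a were lower in both depleted arrays, by log2 differences of -1.88 and -0.59 and of -0.55 and -0.52, and the mean of its probe sets turned its direction. The lower ones were the galactosyltransferase B3galt5, Art5, the lipid transfer protein Pitpnc1, Zfp956, the Ras exchange factor Rasgrf1, Epm2aip1 and Swsap1, between -2.19 for B3galt5 and -1.50 for Swsap1. Except for Pitpnc1 and Epm2aip1, they read under the array median in both depleted arrays, and their size depends on the pseudocount too: Art5 read 0.062 and 0.400, and its log2 difference went from -2.53 to -1.45 with a pseudocount of 1. That of Pitpnc1, which read 3.40 and 2.91, went from -1.92 to -1.71. Other probe sets of the lower genes did not all go the same way. That of Art5 gave 0.53 and -0.32, and those of Epm2aip1 -0.56 and 0.61, -0.06 and 0.07, and -0.05 and -0.43. For Rasgrf1, 1 probe set gave 0.15 and -1.48 and a dim one 0.09 and -0.05, 1 of Pitpnc1 gave 0.07 and -0.14, and a dim one of B3galt5 gave -0.24 and 0.50. Among the higher genes, those of Id4 gave 0.999 and 0.12, and 0.22 and 0.01, and a dim one of Dok7 -0.12 and 0.03. Among all of these genes the limma adjusted p was lowest for Art5 and Pitpnc1, at 0.0996. Art5 was called with a pseudocount of 1 or 5 and by eBayes without trend, B3galt5 with a pseudocount of 5, and Chac1 and Dusp4 with the mean of a gene's probe sets.

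Without a test, 158 genes were at least 2-fold from wild type in both depleted arrays, 100 higher and 58 lower, and 10 of them lie on X or Y. Scaling to named genes with a mean of at least 5, chosen after the data were seen, gave 69 higher and 87 lower. Singling out the first depleted array in the same way gave 307 genes, and the second 199. Between the depleted arrays 1076 genes were 2-fold apart, against 763 between wild type and the first and 618 between wild type and the second. The depleted arrays were therefore no closer to each other than to wild type. With the first depleted array set against the other arrays limma called 74 genes, and with the second set apart it called 0, with 1252 genes at an unadjusted p under 0.05. These counts moved with the scaling: the first gave 142 with the same 75th percentile per array, 14 scaled to named genes with a mean of at least 5 and 7 with quantile normalization, and the second 16, 0 and 0.

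Notch target genes did not fall as a list. Their median log2 difference was 0.16 in the first depleted array and 0.74 in the second over 6 tested genes (camera adjusted p = 0.231). Among matched random lists these medians lay at the 77.2 and 99.5 percentiles. Hes1, a repressor activated by Notch, read 2.93 in wild type and 2.23 and 2.78 in the depleted arrays. Nrarp, a feedback inhibitor of Notch, read 3.47 against 6.89 and 8.26, and Hey1 0.334 against 0.887 and 1.36, while Dtx1 read 1.32 against 0.799 and 1.15. The wild type value of Hey1 lies close to the pseudocount, so the size of its difference depends on it. None of the 6 was called over all genes, and the count adjusted over the list alone was 0. Notch receptors, ligands and cofactors had medians of -0.08 and 0.38 (camera adjusted p = 0.779), with Ncstn, a gamma-secretase subunit, at 12.2 against 21.1 and 21.5.

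Goblet cell markers rose as a list, by a median of 0.64 over 23 tested genes (camera adjusted p = 6.61e-09). With an estimated correlation the camera adjusted p = 0.895. That test has 1 residual degree of freedom and called the simulated raised list in 0 of 20 runs. Its values, here and for the lists below, therefore decide nothing. All 23 were higher than wild type in the first depleted array, with a median of 0.78. In the second 17 were, with a median of 0.31, at the 56.3 percentile of matched random lists. The rise of the list thus rests largely on the first. The first depleted array also had the highest ratios of 3' to 5' control probe sets, a sign of RNA quality: 2.28 for Gapdh against 1.83 in wild type and 1.54 in the second, and 1.15 for Actb against 1.11 and 1.02. B cell markers had a median of -0.93 in the same array. Tff3, a trefoil peptide of mucus, read 52.8 in wild type and 122 and 88.4 in the depleted arrays, and Agr2, which folds mucins, 55.8 against 94.8 and 93.6. Galnt12 read 4.40 against 9.06 and 7.82. Muc2, the main intestinal mucin, chosen after its values were seen, read 67.2 against 127 and 62.6. No goblet marker was called singly, and the count adjusted over the list alone was 0.

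Secretory lineage transcription factors also rose as a list, by a median of 0.50 over 14 genes (camera adjusted p = 0.0329, and adjusted p = 0.895 with an estimated correlation). The medians of the separate arrays were 0.44, with 13 of 14 genes higher than wild type, and 0.17, with 8 higher and at the 41.7 percentile of matched random lists. The list thus rests on the first depleted array, which had the highest 3' to 5' ratios and in which B cell markers had a median of -0.93. The list was not called with no intensity filter, with the filter at the 60th percentile or with a mean of at least 5. Nkx2-2, an enteroendocrine factor, read 0.307 in wild type and 1.17 and 1.52 in the depleted arrays. Foxa2 read 0.609 against 1.82 and 1.30, and Foxa3 3.82 against 8.16 and 6.57. In wild type Nkx2-2 lies close to the pseudocount and Foxa2 under the array median, so the size of their differences depends on the pseudocount. Spdef, needed for goblet cell maturation, read 2.38 against 5.18 and 2.46. Atoh1, which commits cells to the secretory lineage and is held down by Hes1, read 3.73 against 5.09 and 1.89. None was called, and the count adjusted over the list alone was 0.

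No list of the other secretory lineages passed the set test with the main settings. Paneth cell markers passed it with the filter at the 60th percentile and with a mean of at least 5, and had an adjusted p = 0.895 with an estimated correlation and the main settings. Enteroendocrine markers had medians of 0.69 and 0.05, with all 21 genes higher in the first and 11 in the second (camera adjusted p = 0.110). The second median lay under that array's median of 0.22 over all genes, at the 4.46 percentile of matched random lists. Nts, for neurotensin, read 13.0 in wild type and 38.3 and 19.1 in the depleted arrays. Paneth cell markers had medians of 0.57 and 0.17 (camera adjusted p = 0.343), with the protease Mmp7 at 20.8 against 50.8 and 27.4 and the defensin Defa3 at 1.13 against 0.505 and 0.780. Tuft cell markers had medians of 0.51 and 0.13 (camera adjusted p = 0.582). Alox5ap, of leukotriene synthesis, read 2.80 against 4.92 and 4.82, and the receptor Il17rb 2.64 against 2.04 and 1.02. Among matched random lists the Paneth medians lay at the 99.99 and 17.4 percentiles, and the tuft medians at the 99.88 and 36.5 percentiles. The counts adjusted over each list alone were 0.

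**Figure D2:**
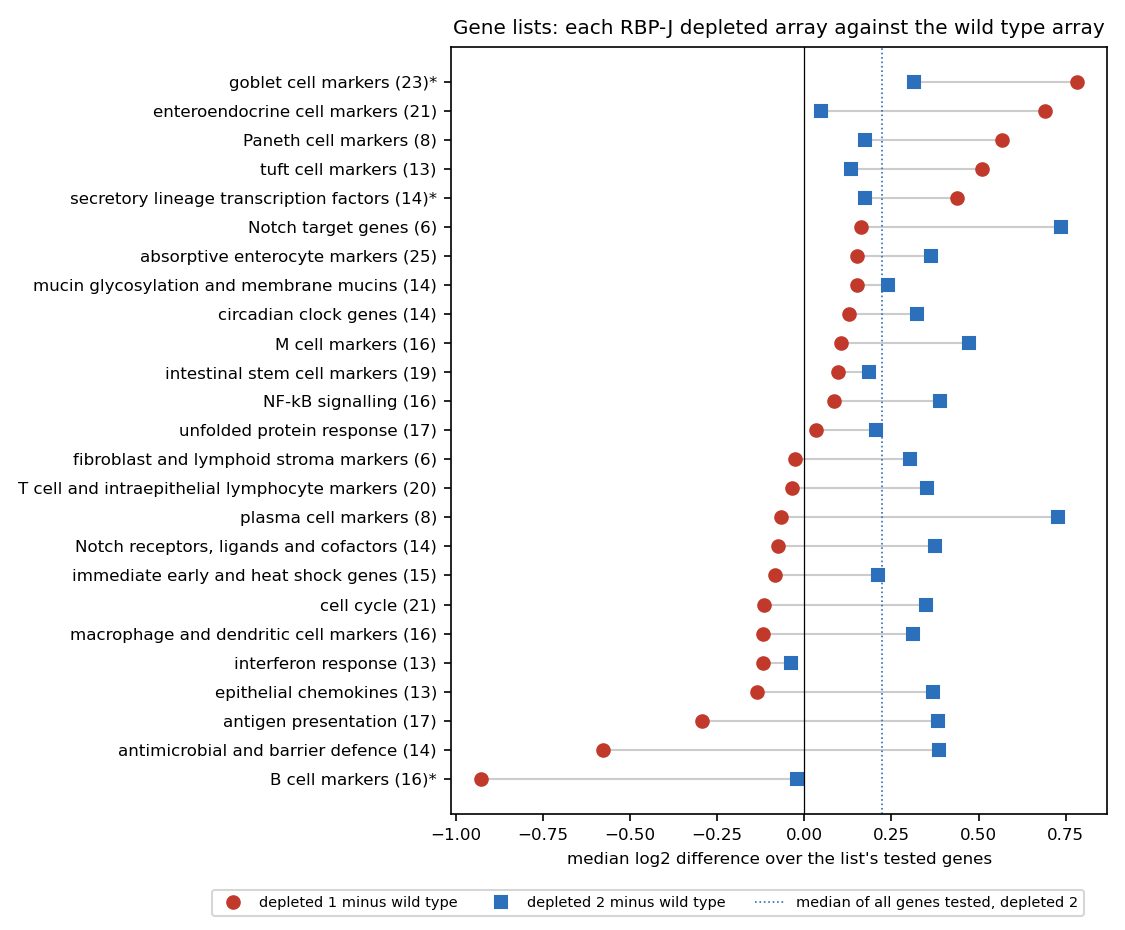
Median log2 difference from the wild type array for each of the 25 lists tested, in the first (circles) and second (squares) depleted arrays, with the number of tested genes in brackets, asterisks on lists called with the preset correlation and a dotted line at the second array's median over all genes. Goblet cell markers lie at 0.78 and 0.31 and B cell markers at -0.93 and -0.02.

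M cell markers, the genes of the antigen-sampling cells of this epithelium, were not called (camera adjusted p = 0.257), with medians of 0.11 and 0.47 over 16 genes, but were with the same 75th percentile per array. With an estimated correlation and the main settings the adjusted p = 0.895. Gp2, a receptor for bacteria on M cells, chosen after its values were seen, read 19.8 in wild type, 9.90 in the first depleted array and 32.6 in the second. Tnfrsf11b, a decoy receptor for the M cell inducer RANKL, read 4.25 against 6.11 and 8.58, and Marcksl1 60.4 against 84.9 and 94.6. A dimmer probe set of Tnfrsf11b gave log2 differences of -0.20 and -0.01. Epithelial chemokines had medians of -0.13 and 0.37 (camera adjusted p = 0.479). Ccl20, which draws CCR6-bearing B cells and dendritic cells to the follicle, read 49.9 in wild type and 45.2 and 74.6 in the depleted arrays. Cxcl1 and Cxcl2, neutrophil chemokines, were lower in both, by log2 differences of -0.97 and -1.10, and not called. NF-kB signalling genes had medians of 0.08 and 0.39 (camera adjusted p = 0.557), with Relb at 7.92 against 10.8 and 12.3. The counts adjusted over each list alone were 0.

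B cell markers fell as a list, by a median of 0.57 over 16 genes (camera adjusted p = 8.53e-06, and adjusted p = 0.895 with an estimated correlation). Ms4a1, the gene of CD20, read 11.1 in wild type and 4.12 and 6.73 in the depleted arrays, the B cell lectin Cd22 4.11 against 1.64 and 2.53, and the complement receptor Cr2 2.01 against 1.04 and 0.949. Ighm, the heavy chain of IgM, and Cd79a, of the B cell receptor, chosen after their values were seen, were higher in the second depleted array, at 13.1 against 9.72 and 27.0 and at 11.1 against 5.85 and 16.7. The median was -0.93 in the first depleted array and -0.02 in the second, so that the value rests largely on the first, the array with the highest 3' to 5' ratios. B cells are not epithelial, and in the first depleted array, where all 23 goblet cell markers were higher than wild type, 2 of the 16 B cell markers were. In the second, 8 of the 16 were higher, and the median of -0.02 lay under that array's median of 0.22 over all genes, at the 6.61 percentile of matched random lists. The count adjusted over the list alone was 0.

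Markers of other cells gave no call. Plasma cell markers had medians of -0.07 and 0.73 (camera adjusted p = 0.429), T cell and intraepithelial lymphocyte markers -0.03 and 0.35 (0.743), macrophage and dendritic cell markers -0.12 and 0.31 (0.582), and fibroblast and lymphoid stroma markers -0.03 and 0.30 (0.582). Lists with fewer than 5 tested genes were not tested as sets. Smooth muscle markers had medians of -0.35 and 0.25 over 4 genes, endothelial markers 0.17 and 0.25 over 3, pancreatic acinar markers 0.26 and 0.23 over 3, and red blood cell markers -0.31 and 0.28 in 1. The 1 tested gene of enteric neurons and glia, the receptor Ret, read 0.811 in wild type and 3.37 and 2.43 in the depleted arrays. It passed when adjusted over the list alone, which for 1 gene is no adjustment, and not over all genes (limma adjusted p = 0.9997).

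Absorptive enterocyte markers had medians of 0.15 and 0.36 (camera adjusted p = 0.0892), with Alpi, intestinal alkaline phosphatase, at 80.1 in wild type and 122 in both depleted arrays. The list was called with the same 75th percentile per array and scaled to named genes with a mean of at least 5, and had an adjusted p = 0.895 with an estimated correlation and the main settings. Antimicrobial and barrier genes had medians of -0.58 and 0.39 (camera adjusted p = 0.231), at the 0 and 83.2 percentiles of matched random lists. Lists without a call were thus also extreme in the first depleted array. Nos2, the inducible nitric oxide synthase, read lower in both without a call (log2 difference -0.71, SE 0.47). Antigen presentation genes had medians of -0.29 and 0.38 (camera adjusted p = 0.479), at the 0.08 and 85 percentiles of matched random lists. Their regulator Nlrc5 read 4.93 against 2.59 and 2.20. The medians of interferon response genes were -0.12 and -0.04 (camera adjusted p = 0.231), with Usp18 at 5.61 against 2.58 and 2.85. Mucin glycosylation and membrane mucin genes had medians of 0.15 and 0.24 (camera adjusted p = 0.479), with C1galt1, which builds core 1 O-glycans, at 33.9 against 49.7 and 48.6. The counts adjusted over each list alone were 0.

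Intestinal stem cell markers had medians of 0.10 and 0.18 (camera adjusted p = 0.731), and of 19 genes 8 were higher and 3 lower in both depleted arrays. Ascl2, a Wnt-driven stem cell factor, read 6.42 in wild type and 2.70 and 3.51 in the depleted arrays. The Wnt target Axin2 read 7.56 against 9.47 and 11.2, but its other probe set gave log2 differences of -0.82 and 0.07. Cell cycle genes had medians of -0.11 and 0.35 (camera adjusted p = 0.582), and of 21 genes 7 were higher and 1 lower in both. The replication helicase subunit Mcm5 read 14.1 against 9.69 and 9.66, and the mitotic kinase Aurka 3.02 against 3.89 and 6.65. A dimmer probe set of Aurka gave log2 differences of -0.51 and -0.23, and one of Mcm5 0.12 and 0.11. A further one of Mcm5 was lower in both. Unfolded protein response genes had medians of 0.03 and 0.21 (camera adjusted p = 0.429), and 1 of 17, Chac1, passed when adjusted over the list alone. Immediate early and heat shock genes had medians of -0.09 and 0.21 (camera adjusted p = 0.101), with Hspa1a and Hspa1b called over all genes and adjusted over the list alone. In the same list, the growth factor response gene Egr1 read 4.39 against 11.2 and 8.89. Circadian clock genes had medians of 0.13 and 0.32 (camera adjusted p = 0.582), with Per1 at 1.47 against 2.73 and 4.19. The counts adjusted over the stem cell, cell cycle and clock lists alone were 0.

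As checks, the 6 tested reference genes had medians of 0.07 and 0.27, and none was called over all genes or adjusted over the list alone. All 4 sex-linked genes passed both. The 18 hybridisation controls, bacterial and phage transcripts added to each sample, had a median log2 difference of 0.08 in the first depleted array and 0.35 in the second.

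**Figure D3:**
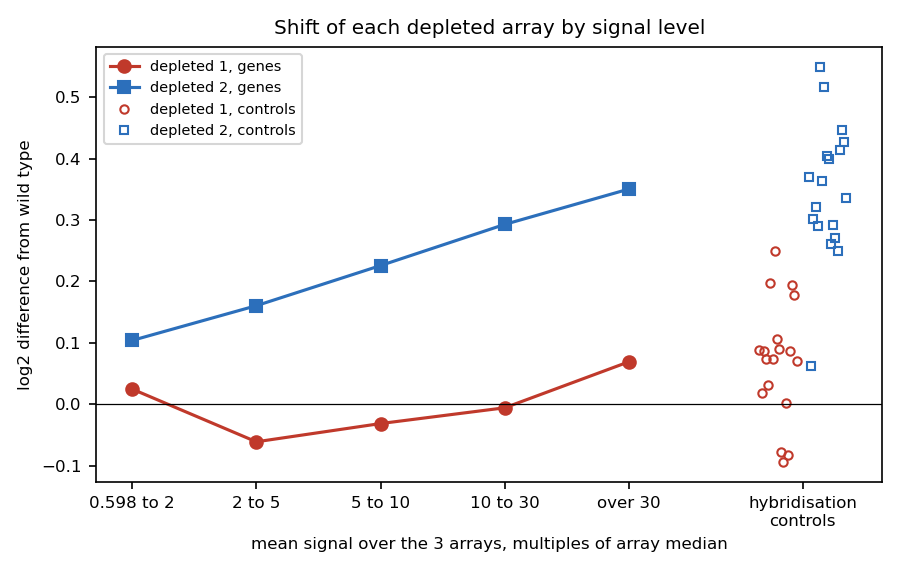
Median log2 difference of each depleted array from wild type over genes grouped by mean signal in multiples of the array median (lines), with each of the 18 hybridisation controls as an open symbol. The second depleted array goes from 0.10 for the dimmest genes to 0.35 for those over 30, and the first from 0.02 to 0.07.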

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

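All tests in this part were chosen after the results they bear on had been seen. A signal appeared in data outside the gene comparisons, in a probe set that the annotation gives to several genes. It read 2.17 in wild type and 8.29 and 6.95 in the depleted arrays, a smaller log2 difference of 1.57. It was the only probe set without a single gene name with a depleted mean of at least 5 and a rise of at least 1.5 in both arrays. That rule cannot flag a fall, and larger falls were present. An unlisted probe set read 5.51 in wild type and 0.015 and 0.004 in the depleted arrays, a pattern like that of Eif2s3y, Kdm5d and Uty. Ddx3y, of the sex-linked list, had no probe set of its own symbol. Whether the unlisted probe set measures a sex-linked gene was not tested. With 1 and 2 arrays per group, no sample could be tested for standing apart within its group.

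Brighter genes read higher in the second depleted array than in wild type, by a median of 0.29 on the log2 scale over genes with a mean of at least 5. RBP-J depletion as the source is argued against by the first depleted array. There the same genes had a median difference of 0.00854 (95% bootstrap interval over genes -0.00326 to 0.0169). That interval resamples genes of 1 pair of arrays, so it gives no spread between samples. The hybridisation controls, which are not mouse RNA, were higher in the second depleted array by a median of 0.3502, with a range from 0.06 to 0.55. This is consistent with the scaling of each array to its median over all probe sets.

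Goblet and enteroendocrine genes were higher in the first depleted array, while in the second goblet genes had a median of 0.31, at the 56.3 percentile of matched random lists, and enteroendocrine genes one of 0.05, at the 4.46 percentile. Fewer lymphoid cells in the first sample would raise all epithelial genes alike if the mix of epithelial cells stayed the same. The goblet and enteroendocrine genes exceeded absorptive enterocyte genes by 0.62 (95% bootstrap interval over genes 0.386 to 0.858). More crypt tissue as a whole would raise stem cell and cell cycle genes as well, and the same genes exceeded those by 0.773 (0.445 to 1.07), although Paneth cell markers, also of the crypt, were higher in the first array by a median of 0.57. The goblet and enteroendocrine genes were picked for their rise in that array, with the medians of the other lists already seen. Both differences were thus known beforehand and decide neither explanation. Less complete RBP-J depletion in the second sample also stays open. In the first depleted array 3 of 3 Rbpj probe sets were lower than in the second. The median log2 difference from wild type over all genes was lower there too, at -0.003 against 0.22. For 1 Rbpj probe set the gap was about as large, at -0.36 against -0.12. B cell genes, from cells that the deletion does not reach, were also lower there, by a median of 0.84 relative to the second. With 1 sample of each kind, a difference between animals or dissections stays open as well and was not tested. The intervals above resample genes, which are not independent, within 1 pair of arrays, so they do not measure the spread between samples.

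Xist was high in both depleted arrays and Y-linked genes in wild type. All 9 probe sets of Eif2s3y, Kdm5d and Uty lay under the array median in both depleted arrays, at 0.393 or less, and all 3 Xist probe sets lay under it in wild type, consistent with a male wild type animal and female depleted animals. For the 6 called genes outside X and Y, which include Mt1, Pla2g4c and Hspa1b, the sex of the animals and RBP-J depletion cannot be told apart, because every array of a genotype shows the same sex pattern.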

How the results depend on the processing

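The alternatives with a mean of at least 5, scaling to named genes, without X and Y and a pseudocount of 5 were chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 replicate numbers, wild type having 1 array. The 10 calls became 4 with quantile normalization and 4 with the same 75th percentile per array, 1 with no filter, 6 with the filter at the 60th percentile, 5 with a mean of at least 5, 5 scaled to named genes with a mean of at least 5, and 5 without X and Y linked genes, where 4 calls could not be tested and Vav3 was lost. Over the other alternatives the count lay between 9 and 14. The 158 genes 2-fold apart in both arrays became 38 with a pseudocount of 1, 38 with one at the median, 7 with a pseudocount of 5, 286 with no filter, 66 with the filter at the 60th percentile and 20 with a mean of at least 5, and were 618 to 763 with 1 depleted array left out, where only 1 array must pass. The share higher was 63.3%, 53.1% with the same 75th percentile per array and 44.2% scaled to named genes. The median over the genes tested in the second depleted array went from 0.22 to 0.02 with quantile normalization and -0.03 scaled to named genes. The 3 called lists became 5 with the same 75th percentile per array, M cell and absorptive enterocyte markers added. They became 0 with an estimated correlation, which with 1 residual degree of freedom also missed the raised list in each of the 20 simulated runs. Absorptive markers were added scaled to named genes, which made 4. Paneth markers took the place of secretory transcription factors at the 60th percentile filter and with a mean of at least 5, and secretory factors were also lost with no filter, which left 2. Goblet and B cell markers were called under each pseudocount, scaling, filter and probe set alternative. The set test was not run with the other eBayes settings or with a depleted array left out. Without the first depleted array the median of goblet markers was 0.31, of secretory transcription factors 0.17 and of B cell markers -0.02. Without the second they were 0.78, 0.44 and -0.93. The cause of these changes was not tested where the alternative's construction does not give it.

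No called gene or list changed direction. Uncalled genes did. With quantile normalization these were Ccl20 at -0.0080, Cxcl16 at -0.011, Cxcl9 at -0.015, Ywhaz at -0.025, Ccl28 at -0.050, Actb at -0.16, Xbp1 at -0.20 and Sdha at -0.24. With the same 75th percentile they were Ccl28 at -0.024, Cxcl9 at -0.035, Bhlha15 at -0.049, Xbp1 at -0.061 and Sdha at -0.065. Scaled to named genes they were Insm1 at -0.013, Sparc at -0.033, Actb at -0.043, Ccl28 at -0.074, Cxcl9 at -0.081, Bhlha15 at -0.091, Xbp1 at -0.11 and Sdha at -0.12. With the mean of a gene's probe sets they were Rgmb at -0.021, Xbp1 at -0.038, Pced1a at -0.071, Ccl28 at -0.077, Ighm at -0.11, Tnfrsf11a at -0.16, Cela3b at -0.19, Ddit3 at -0.31, Hes6 at 0.034 and Cxcl11 at 0.15. Without probe sets that can match several transcripts they were Rrm2 at -0.064, Cdc20 at -0.11, Nfkbie at -0.26, Hes6 at 0.086 and Muc4 at 0.34.

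Uncalled lists whose set test turned direction had these camera adjusted p-values: macrophage and dendritic cell markers 0.486 with no filter, 0.978 at the 60th percentile filter, 0.700 with the same 75th percentile and 0.677 scaled to named genes; T cell markers 0.978 at the 60th percentile filter; the unfolded protein response 0.883 with quantile normalization and 0.513 with a mean of at least 5; antigen presentation and epithelial chemokines 0.901 and stem cell markers 0.990 with a mean of at least 5; and cell cycle genes 0.989 without probe sets that can match several transcripts. The cause was not tested. Of the other tested results for single named genes, 2254 kept direction and side of the threshold, 35 lost the call, 9 of them with no filter, and 7 gained it. Genes that a filter or the choice of probe sets removed are not counted there, so that 7 of the 10 called genes were tested at the 60th percentile filter, 5 with a mean of at least 5 and 9 without probe sets that can match several transcripts. With a depleted array left out there is no test, and of 165 named genes 11 uncalled ones changed direction without the first and 13 without the second. The size of differences of dim genes depends on the pseudocount: Lce3f and Vav3, under it in wild type, lost their call with a pseudocount of 1. Among other settings, they also lost it with quantile normalization, the same 75th percentile and no filter, where their differences stayed of similar size. Whether low signal accounts for those losses was not tested.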

Other observations

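The tests in this part were chosen after the values of some of the genes had been seen, and the genes named here were likewise chosen after the data were examined. The first depleted array alone was at least 2-fold from both others in 6 of 23 goblet cell markers, all higher, and in 4 of 14 antimicrobial and barrier genes, all lower. Retnlb, a goblet cell peptide with antibacterial activity, read 2.61 there against 0.078 in wild type and 0.023 in the second depleted array, and Ern2, a stress sensor of mucus-secreting cells, 5.46 against 1.13 and 0.726. Saa1, an acute phase apolipoprotein, read 5.56 there against 34.0 in wild type and 56.0 in the second depleted array. In all, 117 genes were at least 2-fold higher and 190 at least 2-fold lower in the first depleted array than in both other arrays. Spib, a transcription factor of M cells, read 38.9 in wild type, 33.8 in the first depleted array and 67.6 in the second.

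Fgf15, an ileal hormone induced by bile acids, read 7.65 in wild type and 25.9 and 17.6 in the depleted arrays, without being called (limma adjusted p = 0.644). Hoxb6, the ileal bile acid transporter Slc10a2 and the hormone genes Nts and Pyy were also higher in both. A hypothesis is that the depleted samples came from a more distal part of the small intestine, which no label gives. Over 10 textbook genes of the distal small intestine the median log2 difference was 0.52 in both depleted arrays, but Hoxb6, Slc10a2, Nts, Pyy and Gcg were on that list with their values already seen. The other 5 genes, Cubn, Fabp6, Fgf15, Slc51a and Slc51b, had not been looked at when the list was written, but they were set apart, and the bound that decides the test was set, after their values were seen. They had medians of 0.10 and 0.46, at the 61 and 78.8 percentiles of matched random lists. The 5 proximal genes set apart in the same way, Adh1, Cybrd1, Gata4, Gstm1 and Slc40a1, had medians of -0.0016 and 0.50, at the 42.4 and 87.5 percentiles. In the second depleted array they thus lay above the 5 distal genes. The full lists, with genes already seen, had the reverse order in that array. The 10 distal genes had a median of 0.52, at the 96.85 percentile, and the 10 proximal genes one of 0.41, at the 81.2 percentile. With 5 genes a list, the hypothesis stays open. Among probe sets with several gene names or none, 40 were at least 2-fold higher and 60 at least 2-fold lower than wild type in both depleted arrays.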
